A study of Oryza sativa with 15 samples.

How the data were processed

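Panicles of rice were compared between wild type and an osmads2 mutant at 3 stages set by panicle length, with 3 wild-type and 2 mutant libraries per stage and 15 libraries in all. Per the labels' protocols, total RNA was extracted with TRIzol and treated with DNase I, samples with a RIN over 7 were kept, polyadenylated RNA was enriched, libraries were made with the NEBNext Ultra II kit and sequenced in paired-end mode on an Illumina HiSeq instrument. Per the submitters' processing notes the genome build was IRGSP-1.0 and the tools were FastQC, fastp, featureCounts and edgeR, which the notes list with neither versions nor roles. The aligner, the settings of counting and its use of strand are not given in the sources used here, so reads of overlapping or antisense gene models cannot be told apart.

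The authors deposited a table of counts per gene for the 15 libraries, and these counts entered every test. A header line of that table calls the values normalized, but they are whole numbers with a different total in every library, and they were treated as raw counts. The authors also deposited a table of TPM values; the quantifier behind it is not given in the sources used here. That table holds 37849 genes, of which 37792 are among the 37864 genes of the count table. Of the 25196 genes in both tables with a mean CPM of at least 1, 28.9% (7286) are listed at 0 TPM in all 15 libraries, so the TPM values were used only to define that class of genes. The authors deposited the number of reads and of mapped reads per library, and the share mapped was computed as a percent from those deposited numbers. The authors' tables of changed genes give log2 fold changes, log2 CPM, p-values and adjusted p-values, and per their readme they hold genes with at least a 2-fold change at an adjusted p of at most 0.05. The authors' tables of gene ontology terms give counts of genes per term and −log10 of the adjusted p-value. The authors' table of OsMADS2 ChIP-seq peaks gives each peak's position and the counts of sequence motifs found in it with MEME for 424 genes, of which 216 are in their tables of changed genes; the peak caller, the way peaks were assigned to genes and the build of that table are not given in the sources used here. It also holds 44 blank lines, which were skipped. The authors' tables of regulatory networks were not analysed here.

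Total counts per library ranged from 14713826 to 29387899 with a median of 22697740, and 96.9% to 98.8% of reads were mapped per the deposited read numbers. A gene with 3 counts, the limit that a count of 0 allows, stood at 0.102 to 0.204 CPM depending on the library. Such limits, and the interval given for a ratio of low counts (exact, 95% level), cover counting error only, since the libraries carry no molecular identifiers. The 100 most abundant genes took 10.0% to 11.4% of the counts of a library. Pairs of libraries of 1 group differed by 20.1 to 48.9 times the sampling noise (chi-square per degree of freedom), so no library was present in duplicate within its group. Libraries of different groups were not compared in this way. The labels call the libraries of a group biological replicates.

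Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr, which left 28860 genes, libraries were scaled by TMM (factors 0.977 to 1.06), and a quasi-likelihood model with robust dispersion was fitted to all 15 libraries with 1 mean for each of the 6 groups. With this fit the 2 mutant libraries of a stage borrow their spread from all groups. Contrasts gave the genotype effect at each stage, its average over the stages, its difference between stages on 2 degrees of freedom and between each pair of stages, and the changes between stages in wild type. Adjusted p-values are Benjamini-Hochberg values over all genes of a contrast, and a gene was called at an adjusted p under 0.05. Log2 fold changes are edgeR's. Their standard errors are the size of the log2 fold change divided by the square root of the F statistic, an approximation. CPM values use the TMM-scaled library sizes and are given as mean ± SD. The median log2 fold change of all tested genes was 0.000409 at the early, −0.00801 at the middle and 0.00273 at the late stage. The common dispersion was 0.0605, a biological coefficient of variation of 0.246.

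Gene names came from the authors' tables of changed genes, which pair 853 of 2550 annotated identifiers with a name; the reference table matched 1 identifier. Genes that the authors never listed as changed therefore have no name here, and OsMADS4 and OsMADS16 are not analysed here for that reason. A total of 21 gene lists were fixed before the data were examined, together with the groups, the tests and the alternatives: floral MADS-box, flowering-time, circadian clock, inflorescence and spikelet meristem, anther with tapetum and meiosis, photosynthesis, core cell-cycle, secondary wall and vascular, gibberellin, cytokinin, heat-shock and wounding, and seed storage genes by symbol, and histone, ribosomal protein, auxin response, expansin and xyloglucan endotransglucosylase, lipid-transfer with cutin or wax, kinesin and mitotic, WRKY and pathogenesis-related, terpene and phytoalexin, and transposable element-like genes by description. Core cell-cycle, seed storage, ribosomal protein and kinesin lists matched 0 genes and gave no result. The 25 floral MADS-box symbols gave 1 gene, the 49 meristem symbols 10 and the 44 anther symbols 6. Counts per list are therefore over members with a name, and other members were not looked up in the counts. Since a name here means that the authors called the gene at some stage in these libraries, the counts of list members called are not independent evidence of a change or a direction. Adjustment over the list alone runs over such genes only, so passing it is favoured in advance and is no second test of change. For the same reason camera (limma 3.58.1, preset correlation 0.01, lists of at least 3 members) was run at each stage only on genes named through the tables of the other stages, a departure from the planned test, which assumed names for all genes; fry and camera with an estimated correlation were run beside it.

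The named genes follow a fixed rule. At each stage these were OsMADS2; then, among called genes with a mean CPM of at least 1 at that stage and with every mutant library on the same side of every wild-type library, the 8 largest rises and the 8 largest falls with a symbol or description; then up to 3 called members of each list by smallest adjusted p. For the difference between stages the 6 genes with the smallest adjusted p were taken, and for the wild-type stages up to 4 called members each of the floral MADS-box, flowering-time and anther lists. The rule gave 63 genes. List members named beyond it were chosen after their values were seen. A gene is given with a near-identical neighbour where another model within 3 places in identifier order had counts within 0.25 on the log2 scale in the libraries, at a total of at least 500 counts; counting can split reads between such copies.

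Other settings fixed in advance were RLE size factors (the median-ratio scaling of DESeq2), no filter beyond 1 count, a filter at 1 CPM in 2 libraries, a threshold of 1 on the log2 fold change, the replicate number as a block, a fit to only the libraries compared, limma-voom, DESeq2 1.42.0, each library left out in turn, and a mean CPM of at least 10 for correlations. Without 1 of the mutant libraries a stage has a lone mutant library, which is then assumed to vary like the other groups. Alternatives added after the data had been seen were the scaling of the genes listed at 0 TPM apart from the others, 1 gene of each near-identical group, edgeR's exact test within a stage with and without a 2-fold threshold, every library thinned to the total of the shallowest one, and the test of peaks on other sets of called genes. The exact test with the 2-fold threshold returned the deposited log2 fold changes, with a largest difference of 0.

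Correlations of fold changes are across genes, which are not independent replicates, and each pairs a genotype effect with a wild-type change that shares no library with it. A developmental score placed each library on the line from the early to the late wild-type mean of log2 CPM (prior count 2) over the 3967 genes called between those groups. Membership in the peak table was compared between genes listed as lower and as higher with Fisher's exact test, two-sided. It was compared again among genes of those lists that the quasi-likelihood test called, among quasi-likelihood calls that edgeR's exact test called at any stage, and among the exact test's calls without a fold threshold. The analysis was tested on simulated counts of 28425 genes with 100 genes changed at each fold. At the early stage 34% of genes changed 2-fold and 80% of genes changed 4-fold were called, at the middle stage 35% and 84%, with 4 and 5 false calls and 0 calls at the simulated late stage without any change. Tables were handled with python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.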

Results

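Polyadenylated RNA was sequenced from young panicles of rice (Oryza sativa), the branched inflorescences on which the spikelets form, in wild type and in an osmads2 mutant. OsMADS2 is a PISTILLATA-type MADS-box transcription factor gene, a class that acts in the identity of floral organs. Panicles were pooled by length into an early (0.2 to 0.5 cm), a middle (0.5 to 1 cm) and a late stage (1 to 2 cm), with 3 wild-type and 2 mutant libraries at each stage. In replicate order, the early libraries held 17780525, 18627996 and 18388773 counts in wild type and 14713826 and 16799445 in the mutant. The middle libraries held 29340103, 25659662 and 24300620 counts in wild type and 29387899 and 29220841 in the mutant. The late libraries held 27383919, 22697740 and 19147905 in wild type and 24844034 and 22143863 in the mutant. The early libraries were thus the shallowest. The labels call the libraries of a group biological replicates. The leading principal component of the log2 CPM values held 33.7% of their variance and the next 13.2%.

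The comparison of genotypes asks which genes of the young panicle depend on OsMADS2. OsMADS2 itself (Os01g0883100) was lower in every mutant library than in every wild-type library of its stage. At the early stage it stood at 15.5 ± 3.13 CPM (SD, n = 2) in the mutant and 37.0 ± 5.78 CPM (n = 3; 30.4, 39.3 and 41.2) in wild type, a 2.39-fold difference. At the middle stage it stood at 12.7 ± 0.535 CPM (n = 2; 13.0 and 12.3) against 43.8 ± 3.39 CPM (n = 3; 42.7, 47.7 and 41.2), a 3.46-fold difference. At the late stage it stood at 11.1 ± 0.745 CPM (n = 2; 11.6 and 10.5) against 46.7 ± 5.35 CPM (n = 3; 52.9, 44 and 43.2), a 4.22-fold difference. The log2 fold changes were −1.26, −1.79 and −2.08, each with SE 0.17, with adjusted p of 0.0102, 0.000452 and 0.00022 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. They did not pass edgeR's test of a difference between stages (adjusted p = 0.182). The early call ended without wild-type replicate 2 (adjusted p = 0.0544), mutant replicate 1 (0.0509) or mutant replicate 2 (0.323) of that stage.

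**Figure D1:**
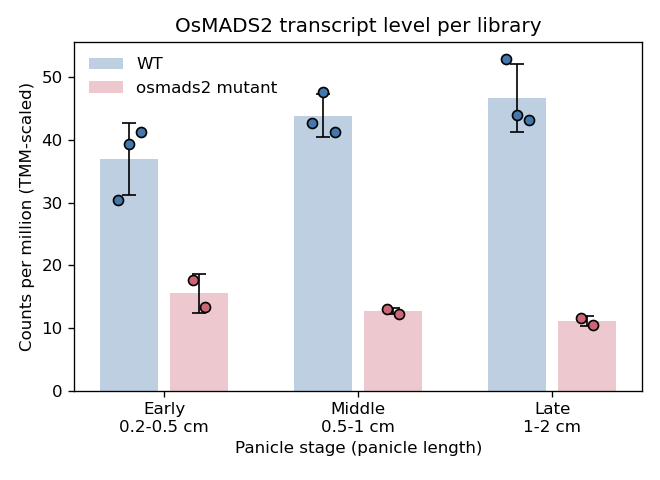
OsMADS2 expression in CPM (y axis) in wild-type and osmads2 panicles at the early, middle and late stages (x axis), with bars at the group mean, error bars of 1 SD and points for single libraries (3 wild type and 2 mutant per stage). The wild-type libraries lie between 30.4 and 52.9 CPM, and every mutant library lies below every wild-type library of its stage.

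In early panicles ROS1B, a DNA glycosylase of the family that removes cytosine methylation, was expressed at 33.9 ± 2.94 CPM in the mutant (n = 2) and 0.391 ± 0.292 CPM in wild type (n = 3), a log2 fold change of 6.44 (SE 0.57, adjusted p = 0.00114). The class III peroxidase prx63 rose by 3.41 on the log2 scale (SE 0.52, adjusted p = 0.0289), to 6.83 ± 2.44 CPM. The receptor-like cytoplasmic kinase RLCK167 rose by 1.32 (SE 0.16, adjusted p = 0.00541), to 29.9 ± 3.71 CPM. TPR42, a tetratricopeptide repeat protein, fell from 13.0 ± 1.8 to 2.24 ± 0.295 CPM (log2 fold change −2.54, SE 0.25, adjusted p = 0.00114). The heat stress transcription factor HSFC1B fell from 6.26 ± 2.07 to 0.763 ± 0.0204 CPM (−3.03, SE 0.42, adjusted p = 0.0141). The amino acid permease AAP6, which has a near-identical neighbouring model, fell from 35.2 ± 5.97 to 15.7 ± 1.22 CPM (−1.16, SE 0.19, adjusted p = 0.0462). edgeR called 13 genes higher and 8 lower in the early mutant, against 2668 genes at an unadjusted p under 0.05. DESeq2 called 97 higher and 165 lower, and limma-voom 14 and 4. Without mutant replicate 2 of the early stage edgeR called 5 genes higher and no gene lower, and 6 of the 7 named calls ended, all but ROS1B (adjusted p 0.06 to 0.391). The calls were 6 and 1 without mutant replicate 1, where 4 named calls ended (0.0509 to 0.539). They were 8 and 4 without wild-type replicate 2, where 4 ended (0.0544 to 0.14). Without wild-type replicate 1, or late wild-type replicate 1 or 3, 13, 17 and 20 genes were lower. The prx63 call ended further without early wild-type replicate 1 (0.0852) or 3 (0.0797), middle wild-type replicate 2 (0.0605) or middle mutant replicate 1 (0.0553) or 2 (0.0533). The AAP6 call ended further without early wild-type replicate 3 (0.0951), middle wild-type replicate 1 (0.0587), 2 (0.0919) or 3 (0.0536), middle mutant replicate 1 (0.0597) or 2 (0.0599), or late wild-type replicate 2 (0.0679).

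Of the 150 named genes matched to the fixed lists, OsMADS2 was the one that edgeR called at the early stage and again at the late stage. It is the single member of the floral MADS-box list with a name here, and it was lower. Among all 150 listed genes 39 had an unadjusted p under 0.05 at the early stage, where DESeq2 called 10 and limma-voom 2. At the late stage 29 had one, and DESeq2 called 8 and limma-voom 7. Adjusted over the list alone, the flowering-time list gave 3 early genes lower: GI and FKF1, which act in the clock's output to flowering, and RCN2, a TERMINAL FLOWER1-type gene. They had log2 values of −2.01, −1.70 and −2.12. GI and FKF1 also count in the clock list, which gave 3 lower with TOC1 (−1.07). Adjusted over the list alone, BHLH142 (0.98) and MIL1 (0.67) of the anther list, the histone H2B gene Os01g0149400 (0.45), and YUCCA3 (1.43) and YUCCA7 (1.87), auxin biosynthesis genes, were higher. On the same terms SAUR21 (−1.49), SAUR25 (−1.02) and SAUR29 (−2.08), small auxin-up RNA genes, and 3 lipid-transfer or cutin genes were lower. The members given here beyond OsMADS2 were chosen after their values were seen. Names came from genes the authors had called in these libraries, which favours passing over the list alone. None of these counts is therefore independent evidence of a change or a direction. At the early stage 0 of 11 lists passed camera in limma, with 1 at an unadjusted p under 0.05. The anther list, upward, had p = 0.00937 and adjusted p = 0.103, or adjusted p = 0.657 with an estimated correlation. The smallest adjusted p by fry was 0.128.

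In middle panicles, the largest rises among genes with a name were again ROS1B, at 34.6 ± 1.77 CPM in the mutant (n = 2) against 0.459 ± 0.439 CPM in wild type (n = 3; log2 fold change 6.16, SE 0.54, adjusted p = 0.000452). The peroxidase prx63 rose as well (4.15, SE 0.53, adjusted p = 0.00124). BGLU30, a beta-glucosidase with a near-identical neighbouring model, rose from 10.5 ± 1.93 to 54.6 ± 16.8 CPM (2.38, SE 0.31, adjusted p = 0.00159). Receptor-like cytoplasmic kinases moved both ways. RLCK14 (2.92), RLCK8 (2.71), RLCK11 (2.15) and RLCK15 (1.96, with a near-identical neighbouring model) rose. RLCK4 (−2.90), RLCK6 (−5.68) and RLCK5 (−7.52, SE 2.00, adjusted p = 0.047, also with a near-identical model) fell. 8TAK1, a receptor-like kinase, also rose (2.83, SE 0.68, adjusted p = 0.0217). The identifiers of 8TAK1 and of these RLCK genes lie in a single stretch, from Os01g0113400 (RLCK4) to Os01g0117000 (RLCK15). They may therefore not be separate observations of the kinase family. None of them passed edgeR's test of a difference between stages (adjusted p 0.258 to 0.943). Among the falls, the glutaredoxin GRX16 went from 5.21 ± 1.34 to 0.555 ± 0.197 CPM (−3.22, SE 0.50, adjusted p = 0.00298). The purine permease PUP13 (−5.43), the small auxin-up RNA gene SAUR24 (−3.72), the glucosyltransferase UGT75J1 (−3.44) and OsLAX5 (−2.88), an AUX1-type auxin carrier, fell as well. UGT75J1 and OsLAX5 have near-identical neighbouring models. edgeR called 1083 genes higher and 2388 lower, with 103 higher and 1450 lower at a threshold of 1 on the log2 fold change. DESeq2 called 1680 and 3256, and limma-voom 1407 and 2481. Without middle mutant replicate 1 the count dropped to 12 higher and 114 lower, and 39 of the 47 named calls at this stage ended (adjusted p 0.0502 to 0.304). Those of OsMADS2, ROS1B, prx63, BGLU30, the histone gene Os01g0149400, YAB3, GELP54 and OsLTP1.17 did not. The counts were 437 and 1571 without mutant replicate 2, 340 and 1298 without wild-type replicate 1, and 331 and 1400 without wild-type replicate 3. Of the genes given here, RLCK6 (0.0577), PUP13 (0.0628) and RLCK4 (0.0542) lost their calls without mutant replicate 2, RLCK14 (0.059) without wild-type replicate 1 and RLCK11 (0.052) without wild-type replicate 2. RLCK5 lost its call in 13 of the 15 fits with a library left out, all but those without late wild-type replicate 1 or 3 (adjusted p 0.0513 to 0.304).

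Of 10 named genes of the inflorescence and spikelet meristem 5 fell in the middle mutant panicles, or 9 adjusted over the list alone. YAB3, a YABBY transcription factor gene, fell from 41.9 ± 1.08 CPM in wild type (log2 fold change −1.23, SE 0.15, adjusted p = 0.000988). FON1, a CLAVATA1-type receptor kinase that limits floral organ number, fell from 21.6 ± 1.38 to 8.87 ± 2.63 CPM (−1.28, SE 0.25, adjusted p = 0.00799). GL1, a WUSCHEL-type homeobox gene, fell from 6.67 ± 2.84 to 1.65 ± 0.0272 CPM (−2.02, SE 0.39, adjusted p = 0.00827). Of 6 anther, tapetum and meiosis genes 4 fell, or 5 adjusted over the list alone. The sporogenesis gene SPL fell from 6.95 ± 0.84 to 1.91 ± 0.634 CPM (−1.86, SE 0.36, adjusted p = 0.00757). BHLH142, a tapetal transcription factor gene (−1.22, SE 0.22, adjusted p = 0.00652), and MIL1, a glutaredoxin gene of early anther cells (−1.25, SE 0.25, adjusted p = 0.0086), fell too. Most calls of other named genes were lower too, with 376 lower and 24 higher beside the meristem list and 377 and 24 beside the anther list. A two-sided Fisher's exact test of the share lower (adjusted p = 1.0) could therefore not have shown a larger share in lists this small. Both lists hold genes the authors called in these libraries, so the counts, also those over the list alone, are not independent evidence of change or direction. Without middle mutant replicate 1 edgeR called 1 meristem gene lower, YAB3, and none of the anther genes. Without mutant replicate 2 it called 3 meristem genes lower. Of the floral MADS-box list OsMADS2 alone had a name, and it fell. The 3 flowering-time genes had 0 calls by edgeR, DESeq2 or limma-voom and 0 adjusted over the list alone. Of these 1 had an unadjusted p under 0.05, and GI and FKF1 had log2 values of −0.24 and −0.31. Of 6 clock genes, ELF4 fell (−1.03, SE 0.21, adjusted p = 0.009) and ELF3.2 rose (1.06, SE 0.30, adjusted p = 0.0404), with the same 1 higher and 1 lower adjusted over the list alone. The ELF3.2 call ended without early mutant replicate 2 (0.0532), middle wild-type replicate 1 (0.0992), 2 (0.0588) or 3 (0.104), or middle mutant replicate 2 (0.14), and both calls ended without middle mutant replicate 1.

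Histone, cell wall and hormone genes made up a further part of the middle-stage falls. Of 5 genes on the histone list 4 fell, or 5 adjusted over the list alone. The H2B gene Os01g0149400 fell from 143 ± 21.1 to 65.0 ± 6.24 CPM (log2 fold change −1.13, SE 0.14, adjusted p = 0.000968) and the H4 gene Os10g0539500 from 310 ± 50.5 to 137 ± 3.51 CPM (−1.18, SE 0.18, adjusted p = 0.00295). Os07g0549900 (−1.36) and PH9 (−1.63, SE 0.26, adjusted p = 0.00361), which the list holds through its description, fell too. Of 8 expansin and xyloglucan endotransglucosylase genes, which loosen or remodel the wall of growing cells, 5 fell, or 6 adjusted over the list alone. Among them were EXPA4 (62.9 ± 1.57 to 31.2 ± 0.243 CPM; −1.01, SE 0.15, adjusted p = 0.00203), XTH28 (−1.22, SE 0.20, adjusted p = 0.00387) and EXPA6 (−1.03, SE 0.22, adjusted p = 0.013). Of 17 auxin genes 9 fell, and adjusted over the list alone 13 fell and 1 rose. Besides SAUR24 and OsLAX5 they included IAA14 (−2.0), an Aux/IAA repressor gene, and GSTU1 (−1.49, SE 0.27, adjusted p = 0.0062), a glutathione S-transferase gene that the list holds through its description. Of 3 cytokinin genes the response regulator RR11 (−1.27, SE 0.32, adjusted p = 0.0258) and LOGL9 (−1.50, SE 0.41, adjusted p = 0.0341), an enzyme of the type that activates cytokinin, fell, and the same 2 genes adjusted over the list alone. Of 6 gibberellin genes 1 fell, OsGASR2 (211 ± 53.7 to 94.7 ± 3.36 CPM; −1.16, SE 0.22, adjusted p = 0.00739), or 4 adjusted over the list alone. These lists too hold genes the authors called in these libraries and are not independent evidence of change or direction, also where adjusted over the list alone. Without middle mutant replicate 1 edgeR called 1 histone gene, the H2B gene, and no gene of the other lists. Without mutant replicate 2 it called 5 auxin genes and 1 cytokinin gene, and without wild-type replicate 1 no cytokinin gene. Without wild-type replicate 3 it called 5 auxin, 3 expansin and 1 cytokinin genes. The RR11 call ended without wild-type replicate 1 (0.0839), and that of LOGL9 without wild-type replicate 1 (0.104) or 3 (0.068) or mutant replicate 2 (0.157). Without middle wild-type replicate 2 there were 3 expansin genes and 2 gibberellin genes. The gibberellin count was 2 also without early wild-type replicate 2 or late mutant replicate 1 or 2, and 3 without early wild-type replicate 3.

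The photosynthesis list, fixed as a marker of leaf-like tissue, had 16 of 17 genes lower and 1 higher in middle mutant panicles, with the same counts adjusted over the list alone. The list also followed panicle stage. From early to middle panicles edgeR called 12 of the 17 genes higher in wild type, and 0 higher and 0 lower in the mutant, a comparison chosen after the data had been seen. LHCA1, a light-harvesting protein of photosystem I, fell from 75.8 ± 20.8 to 25.6 ± 3.51 CPM (log2 fold change −1.56, SE 0.29, adjusted p = 0.00757). PSAK, a photosystem I subunit, fell by 1.54 (SE 0.30, adjusted p = 0.00847) and LHCB3, a light-harvesting protein of photosystem II, fell by 1.35 (SE 0.26, adjusted p = 0.0086). RBCS3, a small subunit of Rubisco with a near-identical neighbouring model, rose (1.93, SE 0.46, adjusted p = 0.0236). Of 29 lipid-transfer and cutin or wax genes 14 fell, and adjusted over the list alone 19 fell and 1 rose. Among them were OsLTP1.17 (−2.50, SE 0.33, adjusted p = 0.00145) and the GDSL lipases GELP54 (28.3 ± 2.66 to 12.6 ± 1.01 CPM; −1.16, SE 0.15, adjusted p = 0.00116) and GELP53 (−1.01, SE 0.14, adjusted p = 0.00181). OsLTP1.17 and GELP53 have near-identical neighbouring models. Of 33 WRKY and pathogenesis-related genes WRKY102 (−1.35, SE 0.20, adjusted p = 0.00202), PR1-21 (−1.05, SE 0.22, adjusted p = 0.0124) and 3 others fell. PR1-51 rose from 3.08 ± 1.03 to 11.5 ± 1.15 CPM (1.91, SE 0.28, adjusted p = 0.00228). Adjusted over the list alone 6 fell and 1 rose. NAC29 (−1.91, SE 0.42, adjusted p = 0.0163), a secondary wall transcription factor gene, fell as 1 of 2 genes of its list. GRP3, a glycine-rich RNA-binding protein gene that was the single member of the transposable element-like list through its description, fell from 4030 ± 765 to 1600 ± 254 CPM (−1.33, SE 0.24, adjusted p = 0.006). DPF, a regulator of diterpenoid phytoalexins and the single member of the terpene list, had 3 counts in the mutant libraries against 29 in wild type, a depth-scaled ratio of 7.14 between wild type and mutant (exact 95% counting interval 2.21 to 36.6; edgeR adjusted p = 0.0202). Of 5 heat-shock and wounding genes edgeR called 0 (limma-voom 0, DESeq2 1; 3 at an unadjusted p under 0.05), and 1 was higher adjusted over the list alone. The names behind these lists came from the authors' calls in these libraries, so the counts, also those over the list alone, are not independent evidence of change or direction.

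All lists together had 3 genes higher and 70 lower of 150 at the middle stage by edgeR, and 5 lower without middle mutant replicate 1. The higher genes were 1 without middle wild-type replicate 2 and 5 without late wild-type replicate 3. A further higher gene came up in the WRKY list without late mutant replicate 1 or 2, in the auxin list without late wild-type replicate 2 or 3, in the heat-shock list without early or late wild-type replicate 3 and in the lipid-transfer list without middle wild-type replicate 1. Without middle mutant replicate 1 edgeR called 2 lipid-transfer genes and no gene of the photosynthesis, WRKY, secondary wall, terpene and transposable element-like lists. Photosynthesis genes called lower were 8 without wild-type replicate 1, 7 without wild-type replicate 3 and 9 without mutant replicate 2, and RBCS3 was not called without wild-type replicate 1 or 2. Lipid-transfer genes called lower were 9 without wild-type replicate 3, and WRKY or pathogenesis-related genes 2 without wild-type replicate 1. The PR1-21 call ended without mutant replicate 2 (adjusted p = 0.0649 by edgeR), and the DPF call without wild-type replicate 3 (0.0521) or mutant replicate 2 (0.118). Against other named genes, 0 of 6 lists passed camera in limma and 0 had an unadjusted p under 0.05. The smallest adjusted p was 0.458, for the auxin list, or 0.697 with an estimated correlation. By fry, which asks whether a list's genes move 1 way on balance, the auxin list passed (adjusted p = 0.0307). Among named genes called at this stage, the share lower differed from that of the other named genes for 0 of 8 lists by two-sided Fisher's exact test (each adjusted p = 1.0). Most of the other named calls were lower, such as 367 lower and 24 higher beside the lipid-transfer list (14 and 0). The test could therefore not have shown a larger share lower in lists of these sizes.

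In late panicles ROS1B (23.7 ± 1.41 CPM in the mutant, n = 2, against 0.176 ± 0.0777 in wild type, n = 3; log2 fold change 6.98, SE 0.61, adjusted p = 0.00042), prx63 (3.54, SE 0.52, adjusted p = 0.0175) and RLCK167 (1.08, SE 0.16, adjusted p = 0.0175) were higher in the mutant by edgeR. TPR42 fell from 11.9 ± 2.94 to 0.938 ± 0.176 CPM (−3.67, SE 0.27, adjusted p = 6.6e-05), and HSFC1B from 5.51 ± 0.406 to 0.804 ± 0.562 CPM (−2.79, SE 0.41, adjusted p = 0.0175). The peroxidase prx118 fell from 37.8 ± 6.9 to 6.3 ± 5.0 CPM (−2.59, SE 0.42, adjusted p = 0.0407) and SAPK9, a kinase activated by abscisic acid, from 47.2 ± 3.45 to 14.1 ± 5.53 CPM (−1.74, SE 0.28, adjusted p = 0.0311). The DnaJ-type chaperone gene OsDjC45 (−5.14, SE 0.83, adjusted p = 0.0311), the serine carboxypeptidase SCP61 (−4.75, SE 0.70, adjusted p = 0.0278) and TPR43 (−1.58, SE 0.23, adjusted p = 0.0175) fell too. edgeR called 13 genes higher and 24 lower at this stage, against 2041 at an unadjusted p under 0.05, DESeq2 42 and 195, and limma-voom 14 and 65. The lower genes were 9 without wild-type replicate 2, and the counts were 8 higher and 7 lower without wild-type replicate 3 and 7 and 7 without mutant replicate 1. Of the 11 named calls, 7 ended without mutant replicate 1 (adjusted p 0.0822 to 0.367), 7 without wild-type replicate 3 (0.0606 to 0.107) and 6 without wild-type replicate 2 (0.0588 to 0.136). There were 4 that ended without mutant replicate 2 (0.053 to 0.309) and 2 without wild-type replicate 1 (0.0554 to 0.075). OsMADS2, ROS1B and TPR42 lost theirs in no such fit. Leaving out a library of another stage ended only calls of prx118 (each of the 10 libraries; 0.0505 to 0.0822), SAPK9 (early wild-type replicate 1 or 2, early mutant replicate 2, middle wild-type replicate 2; 0.0516 to 0.0654) and OsDjC45 (middle mutant replicate 1 or 2; 0.0578 to 0.0581).

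Late members of the anther list had lower values in the mutant, and 5 of 6 passed adjusted over the list alone and none over all genes by edgeR. They were BHLH142 (log2 −0.82), TDR (−1.90), MTR1 (−2.84), MIL1 (−0.70) and YY1 (−3.63). DESeq2 called 3 of this list and limma-voom 2, and 5 had an unadjusted p under 0.05. Adjusted over the list alone, the clock genes PCL1 (−4.37), GI (−1.02) and FKF1 (−1.03), the wall genes EXPA4 (−0.47) and XTH20 (−2.38), the auxin carrier OsLAX5 and 1 gibberellin gene were lower. So were the lipid-transfer genes OsLTP2.2 (−3.96), EPAD1 (−1.14), OsLTPG11 (−2.54) and OsLTP1.17 (−0.92). GI and FKF1 are also the 2 genes lower on the flowering-time list. These members were chosen after their values were seen, and the lists are not independent evidence of change or direction. Of 13 lists 0 passed camera in limma and 2 had an unadjusted p under 0.05. The anther list, downward, had p = 0.00666 and adjusted p = 0.0866, or adjusted p = 0.878 with an estimated correlation. The lipid-transfer list had p = 0.0273 and adjusted p = 0.178, or adjusted p = 0.878 with an estimated correlation. The smallest adjusted p by fry was 0.0621.

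ROS1B, prx63, RLCK167, TPR42, HSFC1B and OsMADS2 were among 16 genes called at all 3 stages, each in the same direction at every stage. The early and middle calls shared 18 genes (2.53 if independent), the early and late calls 16 (0.03) and the middle and late calls 30 (4.45), all with the same direction. These comparisons share no library, although they share the fitted spread. Across genes, which are not independent replicates, the genotype effects correlated with r = 0.304 (rho 0.138) between early and middle, 0.429 (0.219) between early and late, and 0.353 (0.272) between middle and late panicles. For the genotype effect averaged over the stages edgeR called 459 genes higher and 1101 lower in the mutant, 1560 in all, against 7107 at an unadjusted p under 0.05. That number was 397 without middle mutant replicate 1, 575 and 501 without early mutant replicate 1 and 2, 960 and 996 without middle wild-type replicate 1 and 3, and 965 without late wild-type replicate 2. It was 823 and 568 without late mutant replicate 1 and 2.

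The size of the genotype effect differed between stages for single genes, among them a histone gene and a gene of the abscisic acid receptor family. The H2B gene Os01g0149400 had a genotype effect lower by 1.58 on the log2 scale at the middle than at the early stage, as its fall at the middle stage met an early value of 0.45, and the value of the late minus the middle effect was 1.19. PYL/RCAR10, of the abscisic acid receptor family, had differences of −1.80 and 1.55, and Os03g0286500, an RNA recognition motif gene, of −1.81 and 1.59 (each adjusted p = 0.0121 by edgeR on 2 degrees of freedom). Os12g0547100, without a name, had differences of −1.70 and 1.69. edgeR called 221 genes in this test (4293 at an unadjusted p under 0.05), and 215 of these had a middle effect below the early effect. Of the 221 genes, 207 were called lower at the middle stage, 0 at the early and 3 at the late stage. Between pairs of stages, 529 genes differed between middle and early (36 with a higher and 493 with a lower middle effect), 56 between late and middle, and 0 between late and early (1270 at an unadjusted p under 0.05; limma-voom 0, DESeq2 2 higher and 29 lower). The 221 genes became 0 without early mutant replicate 1 or 2 or middle mutant replicate 1, where the calls of the named genes ended as well (adjusted p 0.0519 to 0.0709, 0.0533 to 0.0553 and 0.18 to 0.199). They became 79, 38 and 526 without early wild-type replicates 1, 2 and 3, 23, 360 and 27 without middle wild-type replicates 1, 2 and 3, 49 and 46 without late wild-type replicates 2 and 3, and 52 and 74 without late mutant replicates 1 and 2. The 529 genes became 0 without middle mutant replicate 1, 33 and 55 without early mutant replicates 1 and 2, 231, 195 and 1003 without early wild-type replicates 1, 2 and 3, and 183 and 141 without middle wild-type replicates 1 and 3. They became 330 without late wild-type replicate 3 and 352 and 346 without late mutant replicates 1 and 2. The 56 genes became 0 without middle mutant replicate 1, middle wild-type replicate 1, late wild-type replicate 2 or 3 or late mutant replicate 1, and 1 without middle wild-type replicate 3. They became 11 and 204 without early wild-type replicates 2 and 3, 8 and 16 without early mutant replicates 1 and 2, 179 without middle wild-type replicate 2, 295 without middle mutant replicate 2, 157 without late wild-type replicate 1 and 10 without late mutant replicate 2. The late to early count was 5 without late mutant replicate 2. DESeq2 gave 1382, 1527 and 894 genes for the 221, 529 and 56, and limma-voom 139, 341 and 95, while the replicate number as a block gave 81 for the 221 and 17 for the 56.

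**Figure D2:**
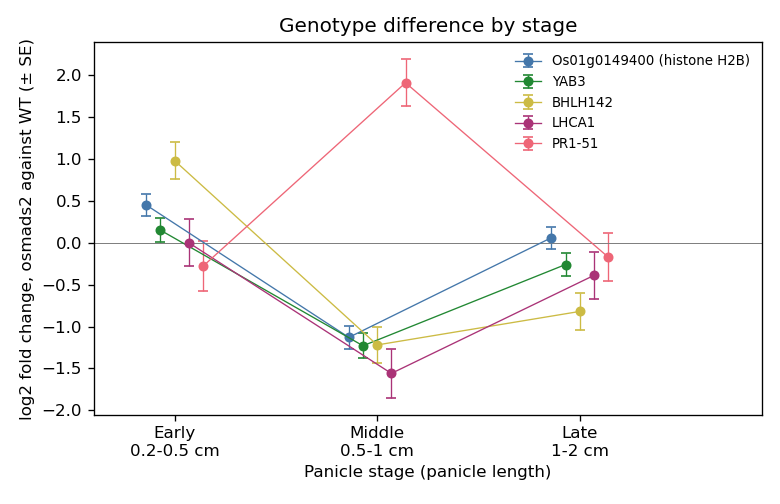
Genotype effect as log2 fold change of osmads2 over wild type (y axis) at the early, middle and late stages (x axis) for the H2B gene Os01g0149400, YAB3, BHLH142, LHCA1 and PR1-51, with points at the edgeR estimate from 2 mutant and 3 wild-type libraries per stage and error bars of 1 SE. At the middle stage the values are −1.13, −1.23, −1.22, −1.56 and 1.91, and the early values of the H2B gene and BHLH142 are 0.45 and 0.98.

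In wild type 5 of 6 named anther, tapetum and meiosis genes rose from the early to the late stage by edgeR, on a list that is not independent evidence of direction. BHLH142 rose from 4.29 ± 1.2 CPM in early to 13.1 ± 2.23 in middle and 35.1 ± 1.42 CPM in late panicles (n = 3 each), by 1.60 (SE 0.20, adjusted p = 0.00221 by edgeR) and 1.43 (SE 0.19, adjusted p = 0.00349) on the log2 scale per step. TDR, a tapetal transcription factor gene, rose from 0.364 ± 0.0164 to 3.54 ± 0.685 and 18.7 ± 3.33 CPM (3.26, SE 0.55, adjusted p = 0.0114, and 2.40, SE 0.44, adjusted p = 0.0183). SPL rose from 2.76 ± 1.21 in early to 10.4 ± 2.69 CPM in late panicles (1.92, SE 0.31, adjusted p = 0.00124), with an early to middle step of 1.33 (SE 0.31, adjusted p = 0.0478), and MTR1, a fasciclin-type glycoprotein gene of anthers, rose by 4.0 (SE 0.65, adjusted p = 0.0104) from middle to late. MTR1 had 3 counts in the early and 675 in the late libraries, a depth-scaled ratio of 178 (exact 95% counting interval 60.7 to 866). MIL1 rose by 1.02 (SE 0.21, adjusted p = 0.0298) from middle to late panicles. edgeR called 531 genes between middle and early (448 higher, 83 lower), 430 between late and middle (370 and 60) and 3967 between late and early (2591 and 1376). No floral MADS-box or flowering-time gene with a name was called by edgeR in any of these comparisons. At an unadjusted p under 0.05 there was 1 flowering-time gene from early to middle, 0 from middle to late and 1 from early to late.

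The early to late calls of BHLH142, TDR, MTR1 and SPL held in each fit with a library left out, and so did both steps of BHLH142. The early to middle call of SPL ended in 12 of 15 such fits by edgeR (adjusted p 0.0502 to 0.138), each but those without early wild-type replicate 3, middle mutant replicate 2 or late wild-type replicate 1. That of TDR ended without early wild-type replicate 1 (0.0592) or 2 (0.0567). From middle to late, the MTR1 call ended without middle wild-type replicate 1 (0.0571) or 2 (0.0803) and the TDR call without middle wild-type replicate 1 (0.073) or 2 (0.128) or late wild-type replicate 2 (0.0722) or 3 (0.0604). The MIL1 call ended without middle wild-type replicate 2 (0.125) or 3 (0.0533) or late wild-type replicate 1 (0.0736), 2 (0.0618) or 3 (0.0738). The 531 genes became 204 and 226 without early wild-type replicate 1 and 2 and 255 and 196 without middle wild-type replicate 1 and 3. The 430 genes became 157 and 113 without middle wild-type replicate 1 and 2 and 185 and 137 without late wild-type replicate 2 and 3. The 3967 genes became 2592 without early wild-type replicate 2 and 2248 without late wild-type replicate 3.

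To ask whether the genotype difference ran along developmental age, each genotype effect was set against a wild-type change that shares no library with it. Across 28860 genes, which are not independent replicates, the middle genotype effect and the change from early to late wild type had r = −0.245 (rho −0.32, covariance −0.1745). The early effect and the change from middle to late had r = 0.085 (rho 0.012, covariance 0.0398), and the late effect and the change from early to middle r = −0.054 (rho −0.025, covariance −0.0191). These were the 3 relations computed. The early value was −0.04 without early wild-type replicate 1 and −0.099 without middle wild-type replicate 1, and 0.147 and 0.161 without early wild-type replicate 3 and late wild-type replicate 2. The late value was 0.083, 0.058 and 0.025 without middle wild-type replicate 1, late wild-type replicate 3 and late mutant replicate 2. On a score that is 0 at the early and 1 at the late wild-type mean, the middle mutant libraries stood at 0.189 ± 0.045 (n = 2; 0.157 and 0.221) and the middle wild-type libraries at 0.464 ± 0.089 (n = 3; 0.464, 0.375 and 0.553), so that both mutant libraries lay below every wild-type library. An exact two-sided permutation test of 2 against 3 libraries gave p = 0.2, the smallest that its 10 groupings allow. The early mutant libraries stood at 0.089 and 0.09 and the late mutant libraries at 0.722 and 0.688, beside wild-type libraries that defined the score.

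**Figure D3:**
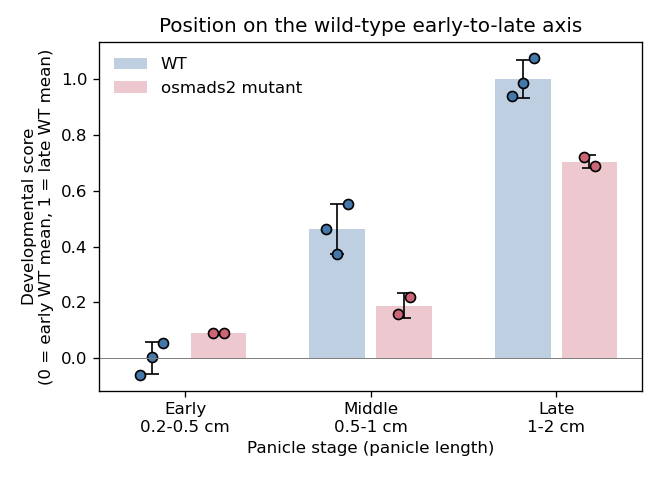
Developmental score (y axis; 0 at the mean of the early and 1 at the mean of the late wild-type libraries, without unit) for each group (x axis), with bars at the group mean, error bars of 1 SD and points for single libraries. The middle mutant libraries lie at 0.157 and 0.221 and the middle wild-type libraries between 0.375 and 0.553.

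The authors' deposited table of changed genes holds 62 genes higher and 314 lower at the early stage, 327 and 1888 at the middle stage, and 30 and 139 at the late stage. edgeR's quasi-likelihood calls included 19 of the 376 early genes, 1487 of the 2215 middle genes and 27 of the 169 late genes, each shared gene with the same direction. In the authors' deposited table of gene ontology terms, the leading term of the genes lower in middle mutant panicles was photosystem II, with 12 of 16 genes (−log10 adjusted p 13.52), and genes higher there had response to flooding, with 14 of 267 (5.5). In the authors' deposited table, genes lower in early mutant panicles had response to molecule of bacterial origin as the leading term (12 of 100 genes, −log10 adjusted p 6.58), followed by chitinase activity (6 of 25 genes, 5.34). Both terms are also listed for genes higher in middle mutant panicles (7 of 100, 3.78, and 4 of 25, 3.73). Genes lower in late mutant panicles had anther development (6 of 151 genes, 4.52). Per the authors' deposited table, 15 early, 78 middle and 6 late genes have an Arabidopsis orthologue that changed in the pi-1 mutant of PISTILLATA.

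Among the 63 named genes, only HSFC1B, OsGASR2, XTH28 and NAC29 are tied to regions bound by OsMADS2 in the authors' ChIP-seq table. Each of them fell in the mutant. HSFC1B, lower at each stage, was tied to a peak on chromosome 1 from 30582047 to 30582832 (786 bp), which held 1 canonical CArG box, the sequence that MADS-box proteins bind. OsGASR2 was tied to a peak on chromosome 4 from 23238666 to 23239066, XTH28 to a peak on chromosome 3 from 7341922 to 7342742, and NAC29 to a peak on chromosome 8 from 857381 to 858183, which held 12 short CGG-repeats. The peaks of OsGASR2 and XTH28 held none of the motifs counted, and that of NAC29 held no canonical CArG box. The table pairs 484 peaks with 424 genes, of which 216 are in the authors' lists of changed genes. Of the peaks, 9 held a canonical CArG box and 233 held short CGG-repeats. At the middle stage 176 of the listed genes lower in the mutant (9.3%) and 16 of those higher (4.9%) had a peak (odds ratio 2.0; two-sided Fisher's exact test p = 0.00751, adjusted p = 0.0225 over 3 stages). At the early stage 25 of 314 lower genes (8.0%) and 0 of 62 higher genes had a peak (p = 0.0211, adjusted p = 0.0316 by the same exact test), and at the late stage 5 (3.6%) and 1 (3.3%; p = 1.0). Among genes of the authors' lists that edgeR's quasi-likelihood test also called, Fisher's exact test gave p = 0.421 at the early stage (1 of the lower and 0 of the higher genes with a peak) and p = 0.0979 at the middle stage (139 and 4 genes). All 424 genes of the table are among the 4447 genes that edgeR's exact test called at any stage without a fold threshold. Among those 4447 genes, 221 of the genes with a lower quasi-likelihood call at the middle stage (10.7%) and 25 of those with a higher call (4.6%) had a peak (two-sided Fisher's exact test p = 6.7e-06, adjusted p = 2.01e-05). The same exact test gave p = 0.4 at the early stage (1 and 0 genes) and p = 1.0 at the late stage (1 and 0 genes). The table's genome build is not given in the sources used here, and its assignment of peaks to genes was taken as deposited.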

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

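The tests of tissue age as part of the difference, of clustering along the chromosomes, of linkage to OsMADS2 and of the spread within stages, the separate scaling of 2 gene classes, the thinning to equal depth and the reading of a mutant library held out were chosen only after the results they measure had been seen.

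The genotype effect of several genes differed between stages by edgeR's test on 2 degrees of freedom, which is what singled them out. The test called 221 genes, and 0 without early mutant replicate 1 or 2 or middle mutant replicate 1, and between 23 and 526 with any other library left out. The H2B gene Os01g0149400, the RNA recognition motif gene Os03g0286500, PYL/RCAR10 and 3 genes without a name had an adjusted p of 0.0121. BHLH142 had 0.0237, YAB3 0.0285 and the lipase GELP54 0.0315. PR1-51 had 0.0359, MIL1 and the H4 gene Os10g0539500 had 0.0362, and the lipase GELP53 had 0.0434, all by edgeR. With the exception of PR1-51, which rose, all of these with a call at the middle stage fell there. For the genotype effect averaged over the stages, chance in the grouping of libraries is argued against, as far as 60 splits can tell. The real grouping gave 1560 genes and the highest of the other groupings 231, so that 1 of 60 splits, the real one, gave as many. The other groupings mix mutant and wild-type libraries, which widens the spread within groups and can lower their counts. For the wild-type stages the 10 splits are too few for a share under 0.05; the real value and the highest other were 531 and 0 from early to middle, 430 and 1 from middle to late, and 3967 and 1 from early to late, each reached by 1 split.

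More genes were lower (2388) than higher (1083) in middle mutant panicles, or 114 and 12 without middle mutant replicate 1. A shift of the genes listed at 0 TPM as a class, seen as −0.24 and −0.12 on the log2 scale in the middle mutant libraries, is argued against as the whole cause, since 67.6% of the calls were lower with the classes scaled separately (746 lower and 519 higher in the class, 1254 and 439 among other genes); with 1 scaling most of the excess lay in the class (1313 and 193, against 1075 and 890), so that a part played by it stays open. Developmentally younger tissue in the middle mutant libraries may be part of the difference: 75.8% of the genes lower there were higher in late than in early wild type, against 45.9% of all tested genes. As the whole difference it is argued against, since of the 114 and 1571 genes called lower with 1 middle mutant library left out 96.5% and 85.2% lay below the early mutant mean in that library, against 47.8% of all tested genes; the share also called lower in middle than in early mutant panicles, 39.4% (941 genes), was 245 of 2014 and 378 of 2088 genes without early mutant replicates 1 and 2 and 33 of 114 without middle mutant replicate 1. Whether the mutation slows the panicle, or whether the pooled panicles differed in age at the same length, was not tested and stays open.

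A set of 52 genes, 16 higher and 36 lower in the mutant, had a log2 difference of at least 2 in the same direction at all 3 stages. edgeR's test of a difference between stages passed for 0 of them. Since the set was chosen for a difference at every stage, this does not show that the effects are equal. The set includes ROS1B and prx63 among the higher genes and RLCK5, RLCK6, PUP13, SCP61 and TPR42 among the lower. A near-identical neighbouring model was found for 3.8% of the set. The criterion asks for close counts in every library, which genes near 0 counts in 1 genotype can miss even where reads are shared. It therefore cannot exclude shared reads, which stay open. Os02g0772100 and Os02g0772150, neighbours by identifier that it did not flag, had middle log2 values of −9.1 and −8.71. Close linkage to the edited gene is argued against for the set as a whole, since 1 gene lies within 100 genes of OsMADS2 (95th percentile of random sets 2, permutation p = 0.31). Linkage over a longer stretch of the chromosome lies outside that window, was not tested and stays open. Local differences between the mutant line and wild type, such as sequence or copy-number variants, may account for part of the set: 14 of its genes have another of the set within 5 genes in identifier order, against a 95th percentile of 4 and a highest value of 12 in 10000 random sets (permutation p = 0.0001, the smallest these sets can give). Shared reads that the criterion missed could add to this clustering. A lasting effect of OsMADS2 on these genes was not tested apart from local differences and stays open.

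Many more genes were called at the middle stage (3471) than at the early (21) and late stages (37). Deeper libraries are argued against: after thinning every library to 14713826 counts, the total of the shallowest, the middle stage gave 847 genes higher and 2096 lower and the early stage 16 and 13, a ratio of 101.5. The lower of the early and late within-stage dispersions (0.0523 and 0.0803) was 1.29 times that of the middle stage (0.0404). The counts above come from 1 fit in which all groups share the spread of each gene. A wider spread at the early and late stages thus does not by itself explain their fewer calls in that fit. It may contribute in fits to only the libraries compared, which called 4 genes at the early, 3299 at the middle and 7 at the late stage. A larger effect of the mutation at the middle stage stays open, and the 221 genes of the test between stages were called 0 times without middle mutant replicate 1.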

How the results depend on the processing

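The scaling of 2 gene classes apart, 1 gene per near-identical group, edgeR's exact test within a stage and the tests of peaks beyond the authors' lists were chosen after the data had been seen. The 65 named calls at the stages kept their direction under DESeq2, both replicate blocks and each left-out library, and the 11 of the wild-type stages under DESeq2, the block over all libraries and each left-out library. DESeq2 kept all 82 calls, and of the fits with a library left out 1051 kept the call and 179 did not, with 0 reversals. RLE size factors, the filters, 1 gene per near-identical group and the class scaling kept each count of calls within 1.5 times, with exceptions. The genes higher for the average (459) were 244 with no filter beyond 1 count, and the 56 genes that differed between late and middle were 18 with the CPM filter and 16 with the class scaling. With 2 mutant libraries per stage, 34% and 35% of simulated 2-fold changes were called at the early and middle stage beside 4 and 5 false calls. A gene without a call is thus not shown to be unchanged, and some calls may be false. The simulation changed 100 genes at each fold and used the same spread in all groups. Its false calls therefore do not give the number of false calls among the 3471 of the middle stage. The cause was not tested for the changes below, except where fewer libraries or a fold threshold make them.

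Genes higher and lower in the mutant were 97 and 165 (early), 1680 higher (middle) and 42 and 195 (late) by DESeq2, and limma-voom gave 4 lower at the early and 65 at the late stage. Fits to only the libraries compared gave 4 and 0 at the early and 3 and 4 at the late stage. edgeR's exact test at 2-fold gave 62 and 314 (early), 327 higher (middle) and 30 and 139 (late), and without the fold threshold 71 and 322 (early) and 30 and 139 (late). A threshold of 1 on the log2 fold change gave 103 and 1450 at the middle stage, 386 genes for the average, 337 from early to middle and 2171 from early to late wild type. DESeq2 gave 3149 genes for the average, 1382 for the difference between stages, 1194 from early to middle and 1064 from middle to late wild type; limma-voom gave 139 for the difference between stages and 743 from middle to late. Between middle and early, late and middle, and late and early effects DESeq2 gave 1527, 894 and 31 genes, and limma-voom gave 341 and 95 for the first pairs. Fits to only the libraries compared gave 106 genes from early to middle and 2155 from early to late.

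Within a stage, no pairing of the genotypes by replicate number was seen: of 6 pairs with the same number and stage 1 had correlated deviations above 0.1 (range −0.449 to 0.105). Deviations are from the group mean, so those of the 2 mutant libraries of a stage are exact opposites. The 6 values are thus not separate checks and do not exclude a pairing. Across stages, wild-type libraries of the same number had 0.084 to 0.187 between early and middle and 0.146 to 0.279 between early and late. Between middle and late they had −0.086 to 0.027. Mutant libraries had 0.389 between early and late, −0.102 between early and middle and −0.153 between middle and late. A link by number across stages therefore stays open. With the replicate number as a block, 598 genes were higher at the middle stage and 6 and 10 were higher and lower at the late stage, the average gave 496, the difference between stages 81 and that between late and middle 17. With a replicate block within each stage, 2 and 1 (early), 3 and 23 (middle) and 2 and 2 (late) genes were higher and lower. Of the named calls, 72 kept their threshold under the block and 4 of 65 under the block within stage. The block within stage leaves few degrees of freedom. Wild-type replicate 3, with no mutant library of its number, no longer enters the comparison there. The fewer calls of that fit therefore do not show that the libraries are paired.

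With a library left out, genes higher and lower ranged from 5 to 16 and 0 to 20 (early), 12 to 1257 and 114 to 2591 (middle) and 7 to 15 and 7 to 33 (late). The average gave 397 to 2085 genes, the difference between stages 0 to 526 (0 to 1003 between middle and early, 0 to 295 between late and middle and 0 to 5 between late and early), and the wild-type stages 196 to 618 (early to middle), 113 to 548 (middle to late) and 2248 to 4246 (early to late). The correlation with the wild-type change ranged from −0.099 to 0.161 for the early, −0.327 to −0.173 for the middle and −0.182 to 0.083 for the late effect. It reversed for the early effect without early wild-type replicate 1 (−0.04) or middle wild-type replicate 1 (−0.099), and for the late effect without middle wild-type replicate 1 (0.083), late wild-type replicate 3 (0.058) or late mutant replicate 2 (0.025). At a mean CPM of at least 10 it was −0.366 for the middle effect and 0.008 for the late effect, a reversal. Of the gene lists, fry called 1 at the middle stage (auxin, adjusted p = 0.0307); camera in limma called 0 to 1 at the early, 0 to 0 at the middle and 0 to 1 at the late stage with a library left out, namely 1 without early mutant replicate 1 (adjusted p = 0.00292), late wild-type replicate 3 (0.048) or late mutant replicate 2 (0.00186). With an estimated correlation and every library in, camera called 0 lists at each stage. Its smallest adjusted p was then 0.657 at the early, 0.697 at the middle and 0.878 at the late stage. Among listed genes that edgeR called, Fisher's exact test of peaks gave p = 0.421 at the early and 0.0979 at the middle stage. Among edgeR calls within the exact test's calls at any stage it gave 0.4 and 6.7e-06, and among the exact test's own calls 0.00715 and 5.53e-06.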

Other observations

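The comparison of middle with early mutant panicles and the list members given in this part were chosen after the data had been seen. From the early to the middle stage 4 of the 5 histone genes fell in the mutant, as did 2 of 10 meristem and spikelet genes. Among the histone genes that fell were the H2B gene Os01g0149400 at a log2 fold change of −1.37 (SE 0.15, adjusted p = 0.000832 by edgeR) and the H4 gene Os10g0539500 at −1.39 (SE 0.20, adjusted p = 0.0032). The homeobox gene GL1 (−2.90, SE 0.42, adjusted p = 0.00357), YAB3 (−1.22, SE 0.16, adjusted p = 0.00201), MIL1 (−2.18, SE 0.27, adjusted p = 0.00181), the cytokinin response regulator RR11 (−2.22, SE 0.35, adjusted p = 0.00515) and EXPA4 (−1.13, SE 0.16, adjusted p = 0.00276) fell too, and so did YUCCA3, an auxin biosynthesis gene (−1.61, SE 0.27, adjusted p = 0.00663). The clock-output genes GI (1.97, SE 0.41, adjusted p = 0.0179) and FKF1 (1.65, SE 0.42, adjusted p = 0.0376) rose. edgeR called 628 genes higher and 1417 lower, with 3 and 28 of the 150 listed genes among them. At a threshold of 1 on the log2 fold change it called 90 higher and 865 lower. DESeq2 called 1122 and 2116, and limma-voom 542 and 1279. The listed genes higher were 0 without middle or early mutant replicate 1, 1 without middle or early mutant replicate 2 and 5 without late wild-type replicate 3. The listed genes lower were 2 without middle mutant replicate 1, 9 without early mutant replicate 1 and 13 without early mutant replicate 2, the meristem genes lower were 0 without middle mutant replicate 1, and the histone genes lower were 1 without middle mutant replicate 1 and 2 without any of the other 3 mutant libraries of these stages. The calls of H2B and MIL1 held in each fit with a library left out. Without middle mutant replicate 1 those of H4 (0.0533), GL1 (0.0696), YAB3 (0.0514), RR11 (0.088), EXPA4 (0.0533), YUCCA3 (0.0986), GI (0.16) and FKF1 (0.206) ended, with 63 genes called in all. Without early mutant replicate 1 (288 genes in all) those of RR11 (0.0519), YUCCA3 (0.0619), GI (0.108) and FKF1 (0.0699) ended, and without early mutant replicate 2 (537) those of GI (0.118) and FKF1 (0.22). Without middle mutant replicate 2 (1050 genes) or late wild-type replicate 2 the FKF1 call ended as well (0.0821 and 0.0552).

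In wild type, of 17 photosynthesis genes 12 rose from early to middle and 15 from early to late, among them LHCA1 (log2 fold change 1.55, SE 0.26, adjusted p = 0.0109 by edgeR, and 2.18, SE 0.26, adjusted p = 0.000197) and CP24 (1.66, SE 0.25, adjusted p = 0.0075, and 2.39, SE 0.26, adjusted p = 9.96e-05), both light-harvesting proteins. Of 29 lipid-transfer and cutin genes 17 rose and 2 fell from early to late. EPAD1, a lipid-transfer protein gene of anthers, rose by 5.01 (SE 0.30, adjusted p = 2.85e-06), while the GDSL lipases GELP76 (−4.04) and GELP90 (−1.83) fell. Of this fall 1 gene was left without early wild-type replicate 1, 2 or 3 and none without late wild-type replicate 1 or 3. OsLAX5 rose by 5.54 (SE 0.44, adjusted p = 1.04e-05), GW8, a grain-width transcription factor gene, by 2.67 (SE 0.33, adjusted p = 0.000292) and FON1 by 1.36 (SE 0.22, adjusted p = 0.00115). Early to middle, the photosynthesis genes called were 3 without early wild-type replicate 1, where the LHCA1 call ended (0.0505), or without middle wild-type replicate 1 or 3, 6 without early wild-type replicate 2 and 7 without early wild-type replicate 3. All lists together had 23 genes higher from early to middle, and 7 without early wild-type replicate 1, 10 without early wild-type replicate 2 and 8 without middle wild-type replicate 1 or 3. They had 18 from middle to late, and 8 without middle wild-type replicate 2, 10 without late wild-type replicate 3 and 11 without middle wild-type replicate 1 or late wild-type replicate 2. From early to late they had 55 higher and 6 lower, and 1 lower without early wild-type replicate 2 or late wild-type replicate 3 and 3 lower without early wild-type replicate 1 or 3, late wild-type replicate 1 or late mutant replicate 1 or 2. The authors' calls in these libraries gave these genes their names, so that the counts are not independent evidence of direction.

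Other groupings of the libraries bear on the correlations across genes. On log2 CPM the genotype effects correlated with r = 0.225 between early and middle, 0.351 between early and late and 0.312 between middle and late panicles, against a highest value of 0.293, 0.431 and 0.348 over 100 splits of the libraries within stages. As many as 6, 4 and 3 of the 100 splits, the real one included, reached these values. The middle effect and the early to late wild-type change had r = −0.311 on this scale, with other splits between −0.262 and 0.326. The 10 splits are too few for a share under 0.05.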
